A study of Cereibacter sphaeroides with 15 samples.

How the data were processed

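The study compared gene expression in Rhodobacter sphaeroides (now placed in the genus Cereibacter) with and without hydrogen peroxide, in the wild type and in a strain lacking oxyR. Per the labels, cells were grown at 32 °C in a minimal medium with malate and little oxygen (about 0.85 mg per litre), shaken at 140 rpm, and received 1 mM peroxide 7 or 30 min before collection, and RNA was extracted with hot phenol. Total RNA of 15 samples was measured, 1 array each, in 5 groups of 3. Groups and replicate letters were taken from the sample titles and descriptions.

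The authors deposited 1 table with an intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 summarises the probes of a set into 1 signal and scales each array to a common mean. In the table the mean of every array, after trimming 2% at each end, lay at about 500.1, so by a rule fixed before the data were examined the signals were used as deposited, and a median centring of log2 values and quantile normalization were run as alternatives. Such scaling does not make the rest of the distribution equal, and the 20th percentile of arrays ran from 33.0 to 120.0. No detection calls were used here, so a dim probe set could not be called absent, and saturation was not marked. The 20th percentile of each array served as a floor for fold changes of named probe sets whose arrays of a group all lay at or under it, a choice made after the data were seen.

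Of the 5355 probe sets, the platform annotation gave 1 gene symbol for 539 (514 genes), several for 0 and none for 4813, and 3 spike-in control probe sets were left out. All 515 Entrez identifiers, controls included, were unmatched in the gene table given, so no coordinates are printed and symbols are those of the platform. Unnamed probe sets are given by number. oxyR and catalase are not named in this annotation, so the planned report of their signal on each array was not made, and the planned peroxide list had 0 members, like that of structural RNA. The lists of iron-sulfur assembly (SufC and sufB) and the Calvin cycle (cbbX and cbbR) had 2 genes and were not tested as lists, with neither Calvin cycle gene discussed.

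A probe set was tested if its signal exceeded the 20th percentile of its array on all 3 arrays of at least 1 group, which kept 4405 (518 named). Log2 signals (a signal of 0 set to 0.1, which 8 values needed, none of them tested) were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 15 arrays and an intensity trend in the variance prior, and 7 contrasts were taken. Calls have a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets, two-sided. Counts at an unadjusted p under 0.05, given beside some of them, also hold probe sets that pass when nothing changed. Gene lists were fixed before the data were examined, by symbol pattern (22 lists), and the 18 with at least 3 tested genes were compared by camera with all other tested probe sets, with 1 mean per named gene and a preset correlation of 0.01. The lists were tested again with an estimated correlation and by fry, which asks whether the genes of a list move one way. No list call held with an estimated correlation in any comparison. Because lists go by symbol, hisG, an enzyme of histidine synthesis, and cysT fall among tRNA synthetases, cysS stands in 2 lists, and rpoZ, a core subunit of RNA polymerase, stands among sigma factors.

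Genes were named by a rule fixed beforehand: per comparison, up to 10 named probe sets with the largest rise and 10 with the largest fall among those called, with groups that do not overlap and a higher group mean above the median, 2 unnamed ones in each direction, and for each list the 2 to 4 called members with the smallest adjusted p or, if none was called, the 2 with the highest signal. For the interaction, non-overlap was not asked. Overlaps of calls were set against independent lists, and for comparisons that share arrays the correlation of 100 simulated unchanged sets was computed. Alternatives were the normalizations, no filter or the 40th percentile, log2 of the signal plus 50, no intensity trend, a 2-fold threshold, the replicate block, fits of only the groups compared, array weights and leaving out each array. After the data were seen, fits without the third arrays, with the signal range (highest signal above 40000 or not) as a block, and with every probe set on its own in the list tests were added, as was the correlation, over all tested probe sets, of log2 changes computed apart on the arrays of lower and of higher range.

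The fit was tested on simulated data with the measured means and limma's moderated spreads of 4405 probe sets. For wild type 7 min against control, 33.0% of 100 probe sets changed 2-fold and 84.0% of 100 changed 4-fold were called, for unstressed ΔoxyR against wild type 42.0% and 76.0%, and for the interaction 9.0% and 54.0%. For wild type 7 min against control, camera called a list raised 2-fold in 20 of 20 draws, and any list in 2 of 20 draws with no change. The noise of each probe set was drawn independently. These draws therefore do not show how often camera calls lists of correlated genes when nothing changed.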

Results

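RNA from 15 samples of Rhodobacter sphaeroides, a purple bacterium that can live by respiration or by photosynthesis, was measured on 15 gene expression arrays with 5355 probe sets. The wild type was sampled without hydrogen peroxide and after 7 and 30 min with 1 mM of it, and a strain lacking oxyR (ΔoxyR) was sampled without peroxide and after 7 min. OxyR is a transcription regulator that senses hydrogen peroxide. Each of the 5 groups held 3 arrays, so the number of arrays limits the precision. The values are the deposited array signals, for which the trimmed mean of every array lay at about the same level, while the median signal ran from 142 to 258. Mean medians per group were 217 ± 15.4 in the unstressed wild type, 168 ± 19.9 at 7 min and 233 ± 22.8 at 30 min, against 186 ± 11.6 and 147 ± 6.22 in ΔoxyR (SD, n = 3). Across probe sets, arrays of one group correlated at r = 0.843 to 0.988. The highest signal was above 40000 on 6 arrays, namely the third array of every group and the second at 30 min, and was at most 25253 on the others. Fold changes below are log2 differences of group means ± the standard error from limma, with 4405 probe sets tested and p adjusted by Benjamini-Hochberg. Group signals are means ± SD over 3 arrays. A signal at or under the 20th percentile of its array is called dim below. Where all 3 arrays of a group were dim, the log2 change is given as a bound (at least), against the higher of that percentile and the signal. The labels do not say whether replicate arrays came from separate cultures, so p-values measure the spread between these samples. First and second arrays correlated at 0.988 in the wild type at 7 min and at 0.980 and 0.983 in ΔoxyR without and with peroxide. With the third array of these groups they correlated at 0.885 to 0.921. If such pairs share a culture or processing, the p-values, which count them as separate, are too small. No probe set carries the name oxyR or catalase in the annotation used here, so the deletion itself was not checked.

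The first question was how the wild type responded within 7 min of peroxide. The named genes with the largest rise included those for handling iron and building iron-sulfur clusters. exbD and exbB, inner membrane proteins that power iron uptake across the outer membrane, rose by 3.46 ± 0.27 (adjusted p = 1.66e-06) and 3.12 ± 0.28. The signal of exbD went from 335 ± 73.9 to 3643 ± 531. sufB and SufC, parts of the Suf system that assembles iron-sulfur clusters, rose by 3.45 ± 0.32 and 2.78 ± 0.27. One of a pair of bfr genes, for the iron store bacterioferritin, rose by 2.05 ± 0.23, while the other, at 5485 ± 415 without and 4132 ± 1188 after peroxide, was not called (-0.45 ± 0.24). chrR, the anti-sigma factor of the singlet oxygen response, rose by 2.95 ± 0.39. lexA and recA of the SOS response to DNA damage rose by 1.81 ± 0.17 and 1.64 ± 0.21. In the other direction, dksA, a factor that acts on RNA polymerase in nutrient stress, fell from 3110.1 ± 149.8 to 126 ± 48.4, a log2 change of -4.69 ± 0.70 (adjusted p = 4.00e-04). hemN and bchE, oxygen-sensitive enzymes of haem and bacteriochlorophyll synthesis, changed by -3.32 ± 0.63 and -2.98 ± 0.73. dorS, the sensor kinase of dimethyl sulfoxide respiration, changed by -2.98 ± 0.61, and all 5 probe sets of appA, an antirepressor of photosynthesis genes, by -2.52 to -2.78. flgL of the flagellum changed by -2.64 ± 0.83 at 1 probe set, dim on 1 of 3 arrays at 7 min, and flhB by at least -1.96 at 1 probe set, dim on all 3 (adjusted p = 0.014), while their other probe sets were not called (-1.78 ± 0.72 and -2.56 ± 0.95). The call of flgL was lost with quantile normalization and median centring (adjusted p = 0.0664 and 0.0557) and without unstressed replicates 1 or 2 or 7 min replicates 1 or 2 (0.061, 0.16, 0.176 and 0.0795).

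Of 5 tested genes of iron transport and storage, 3 rose (median 2.05, camera adjusted p = 0.00114, and adjusted p = 0.0731 with an estimated correlation). Among 11 chaperone and protease genes, 5 rose and none fell (adjusted p = 1.81e-05, and adjusted p = 0.0731 with an estimated correlation). They included the membrane protease htpx (2.17 ± 0.28), the disaggregase clpB (2.09 ± 0.29), the redox-regulated chaperone hslO (1.60 ± 0.21) and the protease lon (1.18 ± 0.22). In the list of glucose oxidation and NADPH genes, edd of the Entner-Doudoroff pathway rose by 2.29 ± 0.31 and one eda by 1.13 ± 0.21, while the other eda fell by 0.89 on the log2 scale (list adjusted p = 0.0386, and adjusted p = 0.177 with an estimated correlation). In the citric acid cycle, gltA, fumC and mdh rose by 1.78 ± 0.19, 0.82 ± 0.17 and 0.85 ± 0.20, although the median of its 7 genes was -0.17 as deposited, -0.09 with quantile normalization and 0.20 after median centring (list adjusted p = 0.044, and adjusted p = 0.198 with an estimated correlation). msrA, which repairs oxidised methionine, rose by 1.59 ± 0.28 as the single called gene of 6 in thiol repair (list adjusted p = 0.0239, and adjusted p = 0.178 with an estimated correlation). The glucose oxidation list lost its call with the signal range of the arrays as a block (adjusted p = 0.0527), without the third arrays (0.0554) and without 7 min replicate 3 alone (0.0754). The citric acid cycle list lost it with that block (0.0603), median centring (0.0689) and quantile normalization (0.182), without the third arrays (0.427), and without unstressed replicates 2 or 3 (0.0522 and 0.0532) or 7 min replicate 3 (0.167).

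Bacteriochlorophyll and carotenoid genes lay lower as a list, with 7 of 19 genes lower, none higher and 13 lower when adjusted over the list alone (median -1.19, adjusted p = 7.79e-04, and adjusted p = 0.528 with an estimated correlation). The list also holds their regulators, and the repressor ppsR was among the lower genes at -0.87 to -1.21 over its 5 probe sets, like appA. The list was not called without the third arrays (adjusted p = 0.0554) or without 7 min replicate 3 alone (0.102). None of the 7 photosystem protein genes was called by limma at this time, and their median was -0.02 as deposited and 0.35 after median centring (list adjusted p = 0.671). The ribosomal protein list of 45 genes was called as higher against other genes (adjusted p = 0.00324, and adjusted p = 0.61 with an estimated correlation), with 3 genes higher and 1 lower, but its median turned from 0.22 to -0.09 with quantile normalization, where the call was lost (adjusted p = 0.464). It was also lost without unstressed replicate 2 (0.14) or 7 min replicate 3 (0.174). Of 9 NADH dehydrogenase genes, 4 fell, with nuoN at -1.42 ± 0.20 and nuoG at -1.22 ± 0.22. Further, 2 of 4 ATP synthase genes fell, with one atpD at -0.99 ± 0.23, while another atpD was not called (0.61 ± 0.36). ccoN, the catalytic subunit of a high-affinity oxidase, fell as well (-1.33 ± 0.41), while hemE of haem synthesis stood at -1.12 ± 0.21. In the sulfur assimilation list, one cysE rose by 2.003 ± 0.255, while another cysE was not called (-0.31 ± 0.26). The list holds cysS by its symbol, although cysS is a tRNA synthetase, and it rose by 2.08 ± 0.24. The sulfate transporter genes cysW and cysT changed by -1.40 ± 0.27 and -1.37 ± 0.27. The lists of NADH dehydrogenase, ATP synthase, oxidases, haem synthesis, sulfur assimilation, DNA repair, sigma factors, nitrogen fixation, flagella and tRNA synthetases had adjusted p of 0.0898, 0.355, 0.355, 0.0608, 0.356, 0.166, 0.22, 0.561, 0.166 and 0.145.

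Over all probe sets, 301 were higher and 609 lower after 7 min, or 910 in total. The unnamed probe set 2310, dim without peroxide, rose by at least 4.64 and 3722 by 5.80 ± 0.35, while 4715 changed by -5.02 ± 0.58 and 1354, dim at 7 min, by at least -3.01. The median log2 change of all tested probe sets was -0.29. From the lowest to the highest of 3 equal classes of mean signal it was -0.58, -0.31 and 0.04. A common offset of 0.29 thus does not hold for all values above. As for the direction, 33.1% of the calls were higher as deposited, 53.3% with quantile normalization and 68.6% after median centring. With the signal range of the arrays as a block 1139 probe sets were called. Computed apart on the arrays of lower and of higher range, the log2 changes of the 4405 probe sets correlated at r = 0.453 (Spearman 0.346) across probe sets, which are not independent replicates. The side of higher range rests on 1 array per group here. The count fell to 480 without wild type 7 min replicate 1, 508 without its replicate 2, 536 and 606 without unstressed replicates 2 and 1, and rose to 1375 without 7 min replicate 3.

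**Figure D1:**
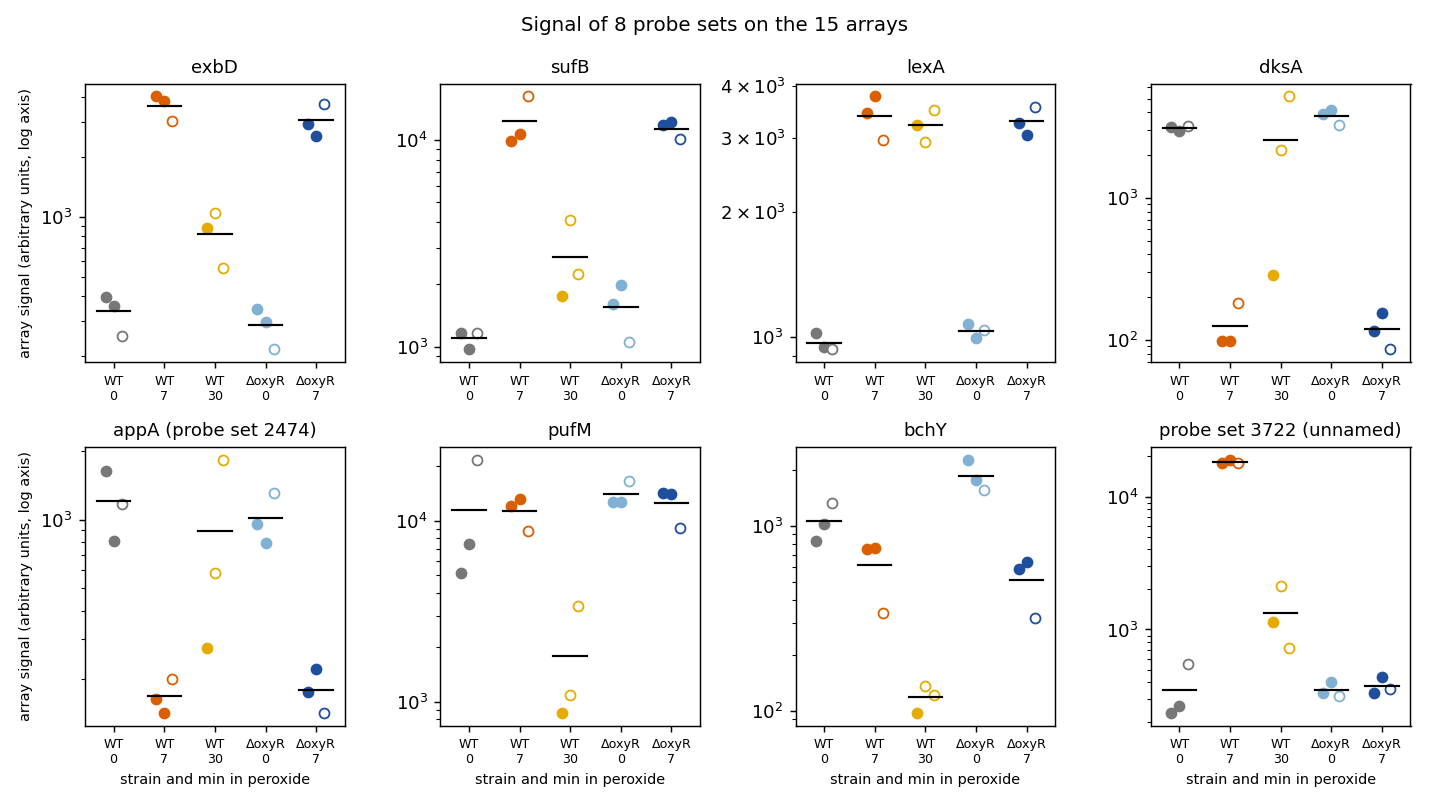
Signal (arbitrary units, log axis) of 8 probe sets on each of the 15 arrays by strain and min in peroxide, with horizontal lines at the group means and open circles for the 6 arrays whose highest signal exceeds 40000. The mean of exbD went from 335 to 3643 in the wild type after 7 min, dksA from 3110.1 to 126, and probe set 3722 from 352 to 18188 in the wild type but only to 378 in ΔoxyR.

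After 30 min of peroxide, 6 of 19 pigment synthesis genes and 3 of 7 photosystem genes of the wild type were lower than without it. With an estimated correlation neither list was called (adjusted p = 0.0851 for both). bchZ and bchY are subunits of a reductase of bacteriochlorophyll synthesis. They fell from 3349.9 ± 1172 to 341 ± 171 and from 1064 ± 257 to 119 ± 19.9, log2 changes of -3.38 ± 0.44 (adjusted p = 9.67e-04) and -3.15 ± 0.34. pucC, an assembly factor of the light-harvesting complex, pufM, a reaction centre subunit, and pufX changed by -2.98 ± 0.49, -2.67 ± 0.52 and -2.33 ± 0.45. crtB and crtC of carotenoid synthesis changed by -2.14 ± 0.28 and -1.31 ± 0.25, and bchC and bchB by -2.84 ± 0.57 and -2.17 ± 0.47. At 30 min bchY and bchC were dim on 1 of 3 arrays. Without 30 min replicate 2, the calls of pucC, pufM and pufX were lost (adjusted p = 0.0604, 0.149 and 0.149). Those of bchC, bchB and crtC were lost as well (0.150, 0.223 and 0.114). bchZ, bchY and crtB kept theirs. lexA and recA rose by 1.73 ± 0.17 (adjusted p = 1.00e-04) and 1.69 ± 0.21, where their 7 min changes were 1.81 and 1.64. SufC and exbD rose by 1.49 ± 0.27 and 1.27 ± 0.27.

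Of the bacteriochlorophyll and carotenoid genes 17 were lower when adjusted over the list alone (median -1.95, adjusted p = 3.47e-30, and adjusted p = 0.0851 with an estimated correlation). Of the photosystem genes 6 were lower adjusted over the list alone (median -2.35, adjusted p = 4.93e-11, and adjusted p = 0.0851 with an estimated correlation). The light-harvesting gene pufA was not called, at -0.14 to 0.01 over its 5 probe sets. Their means were 20834 to 22343 without peroxide and 20462 to 21948 at 30 min. The highest signals of the lower-range arrays, over all groups, were 16075 to 25253. pufA thus lay near the top of the range, and its flat values do not show that it was spared. Lists of haem synthesis and of oxidases were called lower with no single member called (adjusted p = 0.00478 and 0.00894, and adjusted p = 0.117 and 0.269 with an estimated correlation). Lists called higher were DNA repair with 2 of 17 genes called (adjusted p = 0.00105), iron transport with 1 of 5 (0.0133), chaperones with none of 11 (8.93e-04) and flagella with none of 20 (0.0168). With an estimated correlation the adjusted p was 0.104 for the first 3 of them and 0.758 for flagella. The call for flagella was lost with the signal range as a block (adjusted p = 0.242), without the third arrays (0.127), without unstressed replicates 1 (0.315) or 3 (0.0714) and without 30 min replicates 1 (0.414) or 3 (0.141). That for iron transport was lost without the third arrays (0.0551) or 30 min replicate 3 alone (0.0667), that for haem synthesis without 30 min replicate 1 (0.168), and that for oxidases without it (0.462) or unstressed replicate 3 (0.117). The list of 6 nitrogen fixation genes had a median of 0.76 (adjusted p = 0.213). In all, 13 probe sets were higher and 32 lower, 45 in total, with 463 at an unadjusted p under 0.05. The unnamed probe sets 3566 and 2342 rose by 4.45 ± 0.30 and 2.84 ± 0.48, and 1134, dim on 1 of 3 arrays at 30 min, and 2464 changed by -3.48 ± 0.53 and -3.04 ± 0.56.

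The 45 calls were 60 with the signal range as a block, and log2 changes on the arrays of lower and of higher range correlated at r = 0.422 (Spearman 0.323) across the 4405 probe sets. Further, 86 were called with quantile normalization, 16 with only these 2 groups in the fit, 200 without the third arrays and 236 with array weights. Leaving out 30 min replicate 2 left 15, replicate 3 gave 117, and unstressed replicates 3 and 2 gave 18 and 22. Of the 17 probe sets named here, 6 kept the call under each alternative, namely lexA, bchZ, bchY, crtB, 3566 and 1134.

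Between 7 and 30 min in the wild type, dksA and 8 of 20 flagellar genes rose, while exbD, exbB, sufB and chrR, which had risen by 7 min, fell. flhB of the flagellar export apparatus rose by at least 3.02 at 1 of its probe sets, dim on all 3 arrays at 7 min (adjusted p = 0.00341), flgL by 3.43 ± 0.83 at 1 of its own and fliG of the motor switch by 3.19 ± 0.87. dksA went from 126 ± 48.4 to 2550.3 ± 2479, a change of 3.62 ± 0.70 with 30 min arrays at 285, 2167 and 5199. Other flagellar probe sets on this list (flgB, fliK, fliN, flgC, fliM and a further flhB) rose by 2.66 to 3.38. At 7 min flgL and fliG were dim on 1 of 3 arrays and the further flhB on 2. The calls of these 8 flagellar probe sets, leaving aside the first flhB, were each lost when 1 array was left out. Without 7 min replicate 1, flgL had an adjusted p of 0.0648 and the other 7 of 0.0863 to 0.149. Those 7 also lost the call without 7 min replicate 2 (0.0736 to 0.131) or 30 min replicate 1 (0.0774 to 0.119). The calls of flgB, fliK, fliN, flgC and fliM were lost without 30 min replicate 3 (0.0516 to 0.0771), that of fliM without replicate 2 (0.0561), and those of fliK, fliN, flgC and fliM with median centring (0.0516 to 0.0699). exbD, exbB and sufB were lower at 30 min, with log2 changes of -2.18 ± 0.27, -2.13 ± 0.28 and -2.24 ± 0.32. chrR changed by -2.70 ± 0.39 and cysS, a tRNA synthetase, by -2.32 ± 0.24. Photosystem genes pufM, pufX, pufL and puhA stood at -2.92 ± 0.52, -2.79 ± 0.45, -2.27 ± 0.55 and -2.21 ± 0.49, and bchY at -2.30 ± 0.34.

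Of 20 flagellar genes 8 were higher and none lower, or 10 higher when adjusted over the list alone (adjusted p = 0.00769, and adjusted p = 0.545 with an estimated correlation). Their mean log2 signal differed between arrays of one group, at 8.11, 9.81 and 8.48 without peroxide, 6.89, 7.26 and 8.41 at 7 min and 10.59, 8.78 and 9.65 at 30 min. Of 7 photosystem genes 5 were lower (adjusted p = 3.81e-05), of 19 pigment genes 3 were lower and 1, the regulator appA, higher (3.12e-04), and of 5 iron genes 3 were lower (0.00382). With an estimated correlation the adjusted p of these lists was 0.251, 0.459 and 0.163. Further lists called lower were chaperones (5 of 11 lower, 2 higher, adjusted p = 0.00466), glucose oxidation (3 of 5 lower, 1 higher, adjusted p = 0.0382), tRNA synthetases (2 of 16 lower, 1 higher, adjusted p = 0.0307) and ribosomal proteins (6 of 45 lower, 1 higher, adjusted p = 0.00218). With an estimated correlation these had adjusted p of 0.251, 0.251, 0.407 and 0.545. Quantile normalization ended the calls for iron (adjusted p = 0.0636), chaperones (0.289), glucose oxidation (0.114), tRNA synthetases (0.54) and ribosomal proteins (0.205, with the median turned from -0.13 to 0.22). The last 3 of these were also lost without the third arrays (0.077, 0.098 and 0.0603) and without 7 min replicate 3 alone (0.0526, 0.0526 and 0.155), and that of tRNA synthetases without 30 min replicate 3 (0.0778). In total 791 probe sets were higher and 286 lower at 30 than at 7 min, 1077 in all. Among unnamed probe sets, 2339, dim at 7 min, rose by at least 2.90 and 4715 by 4.996 ± 0.583, and 2690 and 2310, each dim on 2 of 3 arrays at 30 min, changed by -4.57 ± 0.58 and -4.06 ± 0.42.

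All probe sets together shifted by 0.36 on the median. From the lowest to the highest of 3 equal classes of mean signal the median was 0.88, 0.34 and -0.13. Higher calls in these classes numbered 365, 293 and 133, and lower calls 11, 48 and 227. The excess of higher calls thus lay outside the brightest class, where more were lower. The higher share of 73.4% was 47.6% with quantile normalization (323 higher and 355 lower) and 28.5% after median centring. With the signal range as a block 1228 were called, and log2 changes on the arrays of lower range correlated with those on the arrays of higher range at r = 0.339 (Spearman 0.301) across probe sets. Only 439 were called with these 2 groups alone in the fit, 385 and 400 without 7 min replicates 1 and 2, 675 without 30 min replicate 1 and 1723 without 7 min replicate 3.

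Without peroxide, the question was what the loss of OxyR changed by itself, and limma called no single probe set between the strains, with 519 at an unadjusted p under 0.05. Among named genes, lexA differed by 0.10 ± 0.17 and recA by -0.05 ± 0.21, or 0.17 after median centring. pufA, a light-harvesting protein, differed by 0.42 ± 0.60 at 1 of its 5 probe sets and by 0.05 to 0.19 at the others. grxC, a glutaredoxin, differed by 0.58 ± 0.22. nifS of nitrogen fixation, dim on 1 of 3 ΔoxyR arrays, differed by -1.44 ± 0.47 (adjusted p = 0.236). As lists, pigment synthesis (median 0.37, adjusted p = 4.43e-05), photosystem (median 0.56), chaperones (0.20), thiol repair (0.26), sulfur assimilation (0.18) and ribosomal proteins (0.05) were called higher in ΔoxyR. Nitrogen fixation (median -1.08) and flagella (-1.42) were called lower, with adjusted p of 0.00339 and 0.00226. The nitrogen fixation list holds dim signals. Its gene nifN averaged 65.9 in the wild type and 22.1 in ΔoxyR, where the mean 20th percentiles were 66.3 and 42.0. The size of such differences is thus limited by the floor. The other adjusted p were 0.00458 for photosystem, 0.00226 for chaperones, 0.00813 for thiol repair, 0.00521 for sulfur assimilation and 0.00273 for ribosomal proteins. With an estimated correlation the adjusted p was 0.227 for nitrogen fixation, chaperones and thiol repair, 0.339 for sulfur assimilation, 0.564 for photosystem and pigment synthesis and 0.762 for flagella and ribosomal proteins. The median of all tested probe sets was -0.16 here, and after median centring the list medians were 0.60 for pigment synthesis, 0.43 for chaperones, 0.48 for thiol repair, 0.41 for sulfur assimilation and 0.27 for ribosomal proteins. With quantile normalization they were 0.07 for chaperones, 0.10 for sulfur assimilation and -0.54 for nitrogen fixation. There the calls for photosystem and ribosomal proteins were lost (adjusted p = 0.102 for each), and the ribosomal median turned to -0.12. Photosystem was also lost without wild type replicates 1 (0.134) or 2 (0.0518) or ΔoxyR replicate 3 (0.0535). Ribosomal proteins were lost without the third arrays (0.11), wild type replicate 2 (0.782) or ΔoxyR replicate 3 (0.701), and flagella without wild type replicate 2 (0.0843) or ΔoxyR replicate 1 (0.332). Flagellar mean log2 signals were 6.06, 6.97 and 9.20 on the unstressed ΔoxyR arrays. Those of pigment synthesis were 10.29, 10.28 and 10.87 in the wild type and 11.07, 10.88 and 10.69 in ΔoxyR. Those of photosystem were 12.00, 12.34 and 13.57 against 13.08, 13.09 and 13.37. In both lists ΔoxyR was higher on the first and second arrays and lower on the third. Between the arrays of lower and of higher signal range the strain differences of all tested probe sets correlated at r = 0.0259 (Spearman 0.026) across probe sets. The count of 0 also held with the range as a block, but was 28 without an intensity trend in the variance, 811 without the third arrays, 1050 with array weights and 4 without ΔoxyR control replicate 3.

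In ΔoxyR, 7 min of peroxide raised exbB, exbD, sufB and chrR, as in the wild type. exbB and exbD rose by 4.22 ± 0.28 (adjusted p = 3.14e-07) and 3.44 ± 0.27, with exbB going from 157 ± 1.80 to 2934 ± 338. sufB and chrR rose by 2.91 ± 0.32 and 3.28 ± 0.39. edd and htpx rose by 2.52 ± 0.31 and 2.32 ± 0.28, and leuC of leucine synthesis by 2.06 ± 0.22. cysS rose by 1.95 ± 0.24, glmU of cell wall precursor synthesis by 1.84 ± 0.25 and selD, which makes selenophosphate, by 2.16 ± 0.59 (dim on 1 of 3 unstressed arrays), a call lost without unstressed ΔoxyR replicate 3 (adjusted p = 0.0585). dksA fell from 3759 ± 443 to 119 ± 35.1, a change of -5.02 ± 0.70. hemN, dorS, bchE and rimM, a ribosome maturation factor, stood at -3.12 ± 0.63, -2.86 ± 0.61, -2.79 ± 0.73 and -2.79 ± 0.48. The sulfate transporter genes cysW and cysT stood at -2.99 ± 0.27 and -2.45 ± 0.27, and the 5 probe sets of appA at -2.46 to -2.64. lexA and recA rose by 1.66 ± 0.17 and 1.21 ± 0.21.

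Of 19 pigment synthesis genes 13 fell, or 16 adjusted over the list alone (median -1.62, adjusted p = 1.25e-05, and adjusted p = 0.431 with an estimated correlation), among them crtC (-2.39 ± 0.25) and crtB (-2.31 ± 0.28). The iron list was called higher with 3 of 5 genes higher and 1 lower, the iron transporter feoB, at -1.77 ± 0.46 (adjusted p = 0.0305, and adjusted p = 0.335 with an estimated correlation). Among 11 chaperones 2 rose and dnaJ fell (adjusted p = 0.0305, and adjusted p = 0.349 with an estimated correlation). The iron and chaperone calls were lost with median centring (adjusted p = 0.0598 for both), quantile normalization (0.0825 and 0.11) and without the third arrays (0.0848 and 0.103), and that of chaperones without unstressed replicate 3 alone (0.0626). rpoE, the sigma factor that chrR binds, rose by 1.57 ± 0.30. Of 9 NADH dehydrogenase genes 5 fell and 1 rose (list adjusted p = 0.1), and 3 of 4 ATP synthase genes fell (list adjusted p = 0.246). Altogether 449 probe sets were higher and 808 lower, 1257 in total. The unnamed 2310, dim without peroxide, rose by at least 4.95 and 2454 by 5.34 ± 0.28, while 4720 and 4602, dim at 7 min, changed by at least -3.02 and -3.10. The higher share of 35.7% was 48.5% with quantile normalization and 60.9% after median centring, with a median shift of all probe sets of -0.12. With the signal range as a block 1492 were called, and with array weights 2514. Log2 changes on the arrays of lower and of higher range correlated with each other at r = 0.677 (Spearman 0.64) across probe sets.

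**Figure D2:**
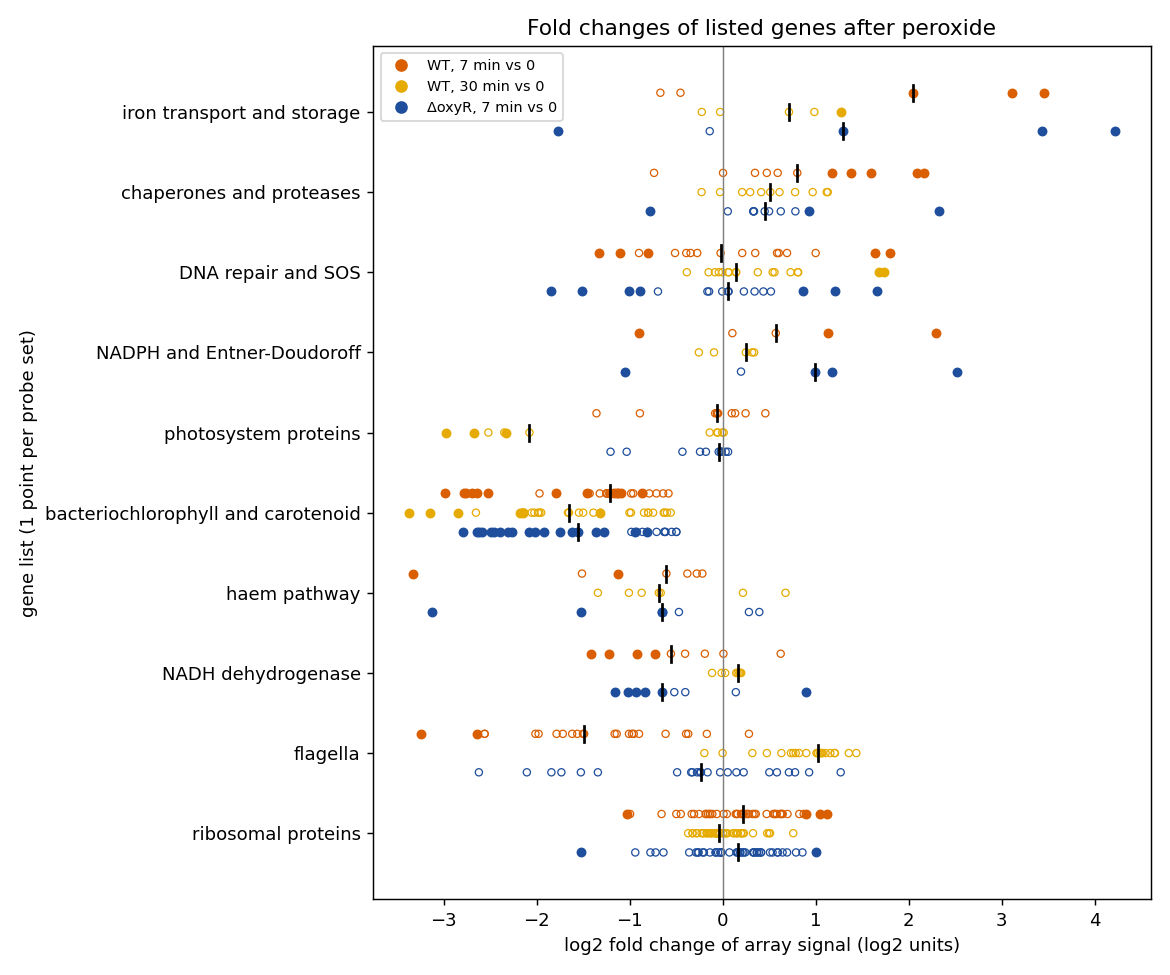
Log2 fold change (horizontal axis, log2 units) of each probe set in 10 gene lists, for the wild type after 7 and 30 min and ΔoxyR after 7 min, each against its own unstressed arrays, with filled points for an adjusted p under 0.05, open points for others and black bars for medians over probe sets. The medians over genes of pigment synthesis lie at -1.19, -1.95 and -1.62, and those of photosystem proteins at -0.02, -2.35 and -0.24, where the first and last turn above 0 after median centring.

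The early responses of the strains, which share no arrays, overlapped in 665 probe sets, with none called in opposite directions. Of these, 228 were higher, where 30.7 would be shared by independent lists, and 437 lower, where 112 would. The calls are not fully independent, because both use the same estimate of the spread of each probe set. Probe sets with a small spread are thus favoured in both lists. The median change was also below 0 in both strains, at -0.29 and -0.12. The counts for independent lists can therefore be too low. exbD, sufB, chrR, edd and htpx rose and dksA, hemN, bchE and dorS fell in both strains. Across the 4405 probe sets, which are not independent replicates, the 2 sets of log2 changes correlated at r = 0.742 (Spearman 0.691). Without the third arrays the overlap was 1133 and the correlation 0.637. The 7 and 30 min changes of the wild type, which share their unstressed arrays, correlated at r = 0.279 against 0.498 in simulated unchanged groups. Their covariance was 0.144 against a simulated 0.0883, a difference of 0.0560. They shared 12 of 13 higher calls (0.888 for independent lists) and 14 of 32 lower calls (4.42), and part of that excess can come from the shared arrays.

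**Figure D3:**
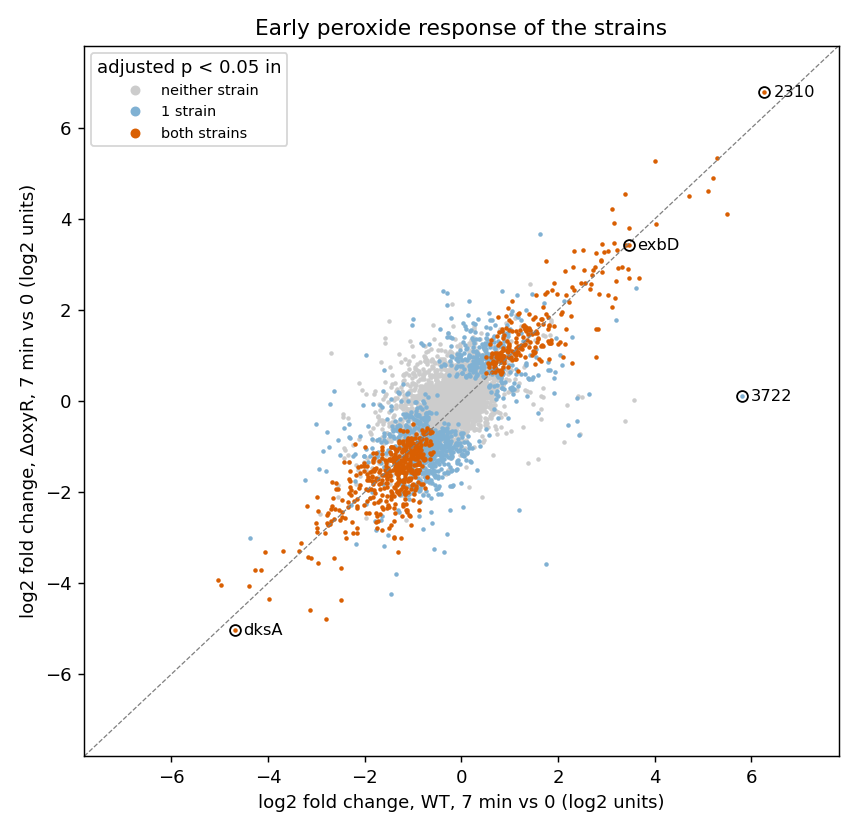
Log2 fold change after 7 min of peroxide in ΔoxyR (vertical axis, log2 units) against the wild type (horizontal axis, log2 units) for the 4405 tested probe sets, coloured by whether the adjusted p was under 0.05 in neither, 1 or both strains, with the diagonal dashed. exbD lies near the diagonal at 3.46 and 3.44, whereas probe set 3722 lies at 5.80 in the wild type and near 0 in ΔoxyR.

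Comparing the strains directly after 7 min of peroxide, the unnamed probe set 3722 stood at 18188 ± 568 in the wild type and 378 ± 57.0 in ΔoxyR, a log2 difference of -5.60 ± 0.35 (adjusted p = 7.87e-07). The unnamed probe set 310 stood at 646 ± 133 and 89.6 ± 6.25 (-2.83 ± 0.36, adjusted p = 0.0018). SufC was lower in ΔoxyR, at -1.28 ± 0.27 (adjusted p = 0.0396), at 2516 ± 554 against 6204 ± 2064. dtd, which removes D-amino acids from tRNA, nuoE of NADH dehydrogenase, repB of plasmid replication, and secA and secY of protein export were lower in ΔoxyR, at -1.71 ± 0.29, -1.61 ± 0.28, -1.52 ± 0.34, -1.34 ± 0.30 and -1.11 ± 0.22. glmS and trpE, of amino sugar and tryptophan synthesis, differed by -0.95 ± 0.21 and -0.95 ± 0.21, while serB of serine synthesis and the unnamed 2934 were higher in ΔoxyR by 0.94 ± 0.21 and 0.85 ± 0.18. lexA and cysS were not called, at -0.04 ± 0.17 and -0.15 ± 0.24 as deposited and 0.15 and 0.03 after median centring. No gene list was called by camera or fry (lowest adjusted p = 0.247, 0 lists with fry), and nuoE was the single called gene of the 9 NADH dehydrogenase genes.

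In all, 2 probe sets were higher and 54 lower in ΔoxyR, with 490 at an unadjusted p under 0.05. Differences on the arrays of lower and of higher signal range correlated at r = 0.195 (Spearman 0.159) across probe sets. The count was 104 with the range as a block, 3 with only these 2 groups in the fit, 21 and 22 with quantile normalization and median centring, 34 without an intensity trend, 199 without the third arrays and 1035 with array weights. It was 9, 10, 12, 24 and 37 without ΔoxyR replicates 2 and 1 and wild type replicates 3, 1 and 2. Of the 12 probe sets named here, 3722 and 310 kept the call under each alternative and the other 10 did not.

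Whether the early response itself differed between strains was asked by the interaction of strain and 7 min of peroxide. A single probe set, the unnamed 3722, was called, with an interaction of -5.69 ± 0.50 (adjusted p = 6.52e-05): it rose by 5.80 ± 0.35 in the wild type and stood at 349 ± 46.3 and 378 ± 57.0 in ΔoxyR. In the wild type at 30 min its arrays read 1146, 2139 and 727. For the other probe sets limma called no interaction. Some named above, chosen here after their values were seen, had large ones, at -2.48 ± 0.50 for the unnamed probe set probe310 and -1.82 ± 0.38 for SufC (adjusted p = 0.115 and 0.115), -1.59 ± 0.38 for cysW, -1.09 ± 0.39 for cysT and 1.10 ± 0.40 for exbB. SufC rose by 2.78 ± 0.27 in the wild type and 0.96 ± 0.27 in ΔoxyR. Interactions were -0.14 ± 0.24 for lexA, -0.43 ± 0.29 for recA, -0.14 ± 0.33 for cysS and -0.76 ± 0.33 for the bfr that rose. Among 11 chaperones the median interaction was -0.29 and among 19 pigment synthesis genes -0.40, both called lower (adjusted p = 0.0457 for each, and adjusted p = 0.837 with an estimated correlation), with no member called. Flagellar genes had a median of 1.05 (adjusted p = 0.0988). Of the 1502 probe sets called in either early comparison, 1413 had the same sign in both and 1 was called for the interaction, or 12 when adjusted within them. The 1502 were chosen by the same estimates that form the interaction, so the 12 are not an independent test. In the tested set 394 had an unadjusted p under 0.05, so a missed call does not show that the strains responded alike. Across probe sets, interactions on the arrays of lower and of higher signal range correlated at r = 0.00707 (Spearman -0.00828). The count was 2 with the range as a block, 403 without the third arrays, 1164 with array weights and 13, 5 and 4 without wild type 7 min replicate 3, ΔoxyR 7 min replicate 3 and ΔoxyR control replicate 3. Both list calls were lost with median centring (adjusted p = 0.0773 for each), with the range as a block (0.0626 for each), and with quantile normalization or every probe set on its own (0.0781 and 0.0567 for chaperones, 0.348 and 0.37 for pigment synthesis). They were also lost without any one of 6 arrays, namely wild type control replicate 2, wild type 7 min replicates 1 and 2, ΔoxyR control replicates 1 and 2 and ΔoxyR 7 min replicate 3, where the adjusted p was 0.0544 to 0.233 for chaperones and 0.0544 to 0.827 for pigment synthesis. Chaperones were lost without ΔoxyR 7 min replicate 2 as well (0.0581), and pigment synthesis without wild type control replicate 1 (0.132).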

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

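The tests of scaling, of the signal range and of a mislabelled array were chosen after the results were seen, and the counts of other splits of the arrays were planned. Probe set 3722, which has no gene name here, differed between the strains in its response to 7 min of peroxide, with an interaction of -5.69 ± 0.50 on the log2 scale. The tables argue against scaling, since the interaction was -5.69 after quantile normalization. They argue against the signal range, since the interaction was -6.12 on arrays of lower range and -4.82 on those of higher range. The latter rests on 1 array per group. They also argue against 1 mislabelled array at 7 min, since the lowest wild type array lay 5.33 above the highest ΔoxyR array. The probe set was picked by its interaction on these same arrays, so none of these values is independent support. That its rise depends on OxyR is a hypothesis that was not tested here, since these data cannot separate OxyR from any other difference between the 2 strains, and no probe set named oxyR checks the deletion. On wild type 7 min arrays 1 and 2 its signal was 93.2% and 89.0% of the highest on the array, and on array 3 it was 44.4%, while its rise was 6.19 on the arrays of lower range and 5.02 on those of higher range.

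For the count of 1 probe set, 11 of 100 splits of the arrays gave as many, with 8 as the highest other, so chance is not excluded for the count. The splits did not weigh the size of this effect.

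The chaperone list and the list of bacteriochlorophyll and carotenoid genes were called as different between the strains in the same test, with median interactions of -0.29 and -0.40. Neither was called with an estimated correlation (adjusted p = 0.837 for both), with quantile normalization, median centring, the signal range or the replicate letter as a block, with every probe set on its own, or without any one of 6 arrays. Of 100 splits of the arrays, 63 called at least as many as these 2 lists, with 8 as the highest other, so chance is not excluded. The wild type response differed between 7 and 30 min at 1077 probe sets. With 10 splits of the 6 arrays, of which 1 gave as many, a share under 0.05 cannot be reached, and the highest other split called 12. Those other splits mix both times within a group, which widens the spread and lowers their counts. The 8 lists called in that comparison stand against 6 in the highest other split, and 1 of 10 splits gave as many.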

How the results depend on the processing

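The fits without the third arrays, with the signal range as a block and with every probe set on its own were chosen after the data were seen. Of 102 named probe set results under 1739 alternatives, 1570 kept direction and call, 169 kept the direction and lost the call and 0 changed direction, with 31 results losing the call at least once, 116 times when 1 array was left out and 53 times otherwise. Counts that moved by over 1.5 times follow, with main values in brackets, and the cause was not tested.

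For probe sets, array weights gave 2666 (910) for the wild type at 7 min, 236 (45) at 30 min, 2690 (1077) for 30 against 7 min, 1050 (0) for the unstressed strains, 2514 (1257) for ΔoxyR at 7 min, 1035 (56) between strains at 7 min and 1164 (1) for the interaction. Without the third arrays the counts were 2193, 200, 2479, 811, 199 and 403 for the same comparisons except ΔoxyR at 7 min, and the overlap of early responses was 1133 (665) and their correlation 0.637 (0.742). Quantile normalization gave 86 at 30 min, 678 for 30 against 7 min and 21 between strains at 7 min, and median centring gave 22 there and 3 for the interaction. Fits of only the groups compared gave 16 at 30 min, 439 for 30 against 7 min and 3 between strains at 7 min. Without an intensity trend 28 were called for the unstressed strains, 34 between strains at 7 min and 2 for the interaction. The interaction had 2 calls with log2 of the signal plus 50 and 2 with the signal range as a block, which gave 104 between strains at 7 min.

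Leaving out 1 array gave 480 to 1375 for the wild type at 7 min, 15 to 117 at 30 min, 385 to 1723 for 30 against 7 min, 0 to 4 for the unstressed strains, 951 to 1127 for ΔoxyR at 7 min, 9 to 73 between strains at 7 min and 1 to 13 for the interaction. Gene lists called with 1 array left out ranged from 3 to 8 (7), 5 to 10 (8), 6 to 10 (8), 5 to 9 (8), 3 to 4 (3), 0 to 2 (0) and 0 to 4 (2) in the same order. The values furthest off came without wild type 7 min replicate 3 (3 of 7), 30 min replicate 1 (5 of 8), and unstressed wild type replicate 2 (5 of 8 between the unstressed strains). Between strains at 7 min, 1 list was called without wild type replicate 3 and 2 without ΔoxyR replicate 3. For the interaction the count of 2 lists became 0 without wild type control replicate 2, wild type 7 min replicates 1 or 2 or ΔoxyR control replicate 1, 1 without ΔoxyR control replicate 2 or ΔoxyR 7 min replicate 3, and 4 without replicate 3 of the wild type control or 7 min arrays. An estimated correlation gave 0 in each of the 6 comparisons that had list calls. fry gave 5 (8) at 30 min, 1 (8) for the unstressed strains, 11 (3) for ΔoxyR at 7 min and 0 (2) for the interaction, and did not call the ribosomal list for the wild type at 7 min. At 30 min the lists it did not call were flagella, haem synthesis and oxidases, for 30 against 7 min pigment synthesis, ribosomal proteins, flagella and tRNA synthetases, and for the unstressed strains all but nitrogen fixation. For ΔoxyR at 7 min, median centring, quantile normalization and leaving out the third arrays each gave 1 (3), and for 30 against 7 min quantile normalization gave 4 (8) and leaving out the third arrays 5 (8). For the interaction both normalizations, the signal range as a block and every probe set on its own gave 0 (2), and leaving out the third arrays gave 5 (2).

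With the replicate block, the letter A, B or C of the titles, the counts of probe sets were 1082, 49, 1326, 0, 1440, 82 and 1, and the 2 lists called for the interaction became 0 (adjusted p = 0.054 for each), with no other count of calls moving by over 1.5 times. Under the block the citric acid cycle (adjusted p = 0.0624) and glucose oxidation (0.0565) were not called for the wild type at 7 min, nor glucose oxidation (0.0593) for 30 against 7 min. No label says that the letters pair the samples, so they were not taken to do so. The 30 pairs of same-letter arrays deviated together at r from -0.186 to 0.513, of which 19 were over 0.1. The median was 0.152 against -0.0583 for different letters, and 9 of 15 arrays correlated best with their own letter, which leaves a factor shared by letter open. Deviations were taken from the group means, which ties the values of different letters to those of the same letter. The -0.0583 is thus no independent baseline. Signal over background limits the sizes of dim probe sets. The 3 control probe sets read 0.1 to 53.9, and 8 of 206 called changes of named probe sets had a group with all arrays at or under the 20th percentile, so that only a bound is given, and 13 had 1 or 2 such arrays.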

Other observations

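Tests of explanations in this part were chosen after the results were seen, and the counts of splits were planned. Between 7 and 30 min in the wild type, single genes of respiration and of the citric acid cycle were called in either direction. Of 9 NADH dehydrogenase genes 5 were higher at 30 min, among them nuoN by 1.57 and nuoG by 1.40, while the list missed the threshold (median 0.76, adjusted p = 0.0536). Of 4 ATP synthase genes 2 were higher (list adjusted p = 0.386). In the citric acid cycle gltA, fumC and mdh were lower, at -1.96, -1.21 and -0.68, and one sdhA was higher at 0.82. The median of that list was 0.41 as deposited and -0.07 after median centring (adjusted p = 0.0536). nifN of nitrogen fixation, dim on 2 of 3 arrays at 7 min, rose by 1.76 ± 0.42, a call that was lost with quantile normalization at 0.82.

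More probe sets were lower than higher after 7 min in both strains. Among the tested probe sets in the highest of 3 equal classes of mean signal 46.1% of the calls were lower in the wild type and 51.8% in ΔoxyR. From the lowest to the highest class, however, the lower calls numbered 178, 259 and 172 in the wild type and 176, 356 and 276 in ΔoxyR, while the higher calls went from 19 to 81 and 201 and from 64 to 128 and 257. The smaller share thus came with more higher calls and does not decide whether unequal distributions left by scaling to a common trimmed mean made the excess. That and a wider fall of dim transcripts in the cell both stay open, because quantile normalization removes either by its construction.

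No probe set was called between the unstressed strains, but 811 were without the third arrays. An additive offset of the third arrays is argued against, because with the signal range as a block 0 were called. For a strain difference held by every array, the signs on the arrays left out cannot decide. Of the 811, 52.4% had the same sign between the arrays left out, relative to the median, against 49.9% of the probe sets not called. For the wild type at 7 min, 69.2% of the 2193 probe sets called without those arrays had the same sign there. Even that response, with more calls, was only partly kept, and a smaller one could lie lower. The share of 52.4% therefore leaves open whether such a difference explains the count of 811. The count of 811 may be explained by replicates 1 and 2 sharing a culture, day or processing. In 4 of the 5 groups this pair had the highest correlation, at 0.980 in unstressed ΔoxyR against 0.888 and 0.889 with replicate 3. In the wild type at 30 min, however, replicates 2 and 3 were closest, at 0.915 against 0.896 and 0.843 for the other pairs. Both are arrays of higher signal range, so in every group the closest pair had the same range. The correlations thus cannot separate a shared culture, day or processing from the signal range. No label tells how the third samples differed.

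Splits of the arrays into other groups of the same sizes were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The other splits mix arrays of both groups, so a real difference adds to the spread within groups and lowers their counts of probe sets. The real counts of probe sets and the highest of the other splits were 910 and 0 for the wild type at 7 min, 45 and 1 at 30 min, 1257 and 0 for ΔoxyR and 56 and 0 between strains at 7 min, each with 1 of 10 splits as high as the real one. For the unstressed strains both were 0, so all 10 splits gave as many. For gene lists they were 7 and 7 for the wild type at 7 min (3 of 10 splits as high), 8 and 9 at 30 min (2 of 10), 8 and 6 for the unstressed strains (1 of 10), 3 and 3 for ΔoxyR at 7 min (7 of 10) and 0 and 4 between strains at 7 min (10 of 10).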
